A study of Mus musculus with 9 samples.

How the data were processed

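The samples were livers of mice in 3 groups of 3 libraries: wild type, Cth knockout, and Cth knockout with 1% betaine in the drinking water. The labels do not say that the replicates of a group are separate animals, so the p-values measure only the spread between samples. They state an NEBNext Ultra kit and give no strand, sex, age or batch. Per the submitters' processing notes the tools were HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1 on genome build mm10, with no role stated for each.

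The deposited table holds 1 FPKM value per gene and library for 54532 genes, made by the authors before deposition, with no raw counts. Symbols were matched for 54409 genes. Exon lengths came from GENCODE M21 (GRCm38, the same assembly as mm10), as the union of a gene's exons, and were found for 54495 genes. With these lengths 98.3% to 98.6% of low values, up to 20 reads, fell within 0.05 of a whole number of reads. The library denominators that this gave were 13513377 to 18528020 reads. Their logarithms correlated with median-of-ratios size factors at 1.0, with a largest gap of 0.0344 log2, and with the recovered read totals at 0.813. The deposited FPKM thus carry a scaling like median-of-ratios factors and are not relative to each library's own read total. Recovered totals were 15184982 to 17473962 reads, sums of FPKM 373773 to 584197, and the 10 most abundant genes held 25.8% to 30.4% of FPKM. A count of 3 reads in a 1 kb gene equals 0.162 to 0.222 FPKM, for counting error only.

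The groups, the tests, the 39 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Genes with a mean of at least 0.5 FPKM over the 9 libraries were tested, 11852 in all. Values were log2(FPKM + 0.5). One linear model with all 9 libraries was fitted in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with trend and robust). The 3 contrasts were knockout minus wild type, betaine-supplemented knockout minus knockout and betaine-supplemented knockout minus wild type. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the 37 lists with at least 4 measured genes, and again with an estimated correlation. With the estimated correlation no list passed in any comparison (lowest adjusted p = 0.973, 0.945 and 0.536 in the order of the contrasts). Many lists share an adjusted value within a comparison, so these values do not rank them. The lowest unadjusted p of this camera run were 0.0481 (clock genes), 0.139 (cholesterol synthesis) and 0.0145 (histone methyltransferases). It used all 9 libraries and no removal of the length trend, so it does not test list calls of other fits. A list's direction is that of its test, and its median, mean and per-member counts stand beside it. Preparation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

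The lists covered methyl and sulfur metabolism (methionine cycle and transsulfuration, folate, choline, glutathione and NRF2), stress responses, lipid, bile acid, glucose, amino acid and xenobiotic metabolism, hepatocyte identity and zonation, sex-biased and sex-chromosome genes, acute phase, inflammation and interferon, markers of the other cell types of liver and of neighbouring tissues, cell cycle and apoptosis, histone lysine methyltransferases and demethylases, the clock, immediate-early genes, mitochondria and ribosomes. Some genes stand in more than 1 list. Named genes were Cth, and in each comparison the 8 largest rises and 8 largest falls among genes past the threshold. These had to have groups that did not overlap in FPKM, which chance gives for 10% of genes with 3 libraries against 3, and a mean of at least 1 FPKM in either group. Predicted gene models and pseudogenes were left out. From each list up to 4 members past the threshold with the smallest p were named, or values of up to 2 members where fewer passed, and up to 6 genes for the reversal. The rule gave 226 genes, some of which are not reported here. The sex-linked and sex-biased genes compared between libraries, and the genes of the feeding and clock lists in the closing part, were chosen after their values were seen.

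The count of genes called in both the knockout and the betaine comparison with opposite signs was set beside 50 simulations without an effect and 50 with the knockout effect and no betaine effect, since both comparisons share the knockout libraries. With 3 libraries these could not be divided between the comparisons. The pipeline was tested on simulated data with 200 changed genes. Changes of log2 0.5, 1 and 2 were recovered in 9.52%, 70.8% and 95.3% of genes for knockout minus wild type, 9.23%, 51.7% and 93.2% for betaine minus knockout and 5.97%, 60.9% and 93.9% for betaine minus wild type, with 4, 7 and 5 false calls and 0 lists called. Moving the ribosomal list by 0.5 gave adjusted p = 1.31e-32 with camera and called 0 other lists. In all these simulations genes varied independently, so they do not test false list calls among genes that vary together. The recovery rates hold for 200 changed genes and not for other numbers.

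Alternatives planned were pseudocounts of 0.1 and 1, no filter, a mean of at least 1 FPKM, median-of-ratios, quantile and TPM scaling, eBayes without trend or robust, array weights, a fit of only the 2 groups compared, the replicate number as a block, each library left out in turn, the estimated correlation, and a log2 fold change of at least 1. Chosen after seeing the data were removal of each library's smooth trend (lowess, span 0.3) along exon length or along exon length and GC content, scaling to each library's own read total, and wild type replicate 3 left out together with the length trend. Other splits of the libraries were counted for each comparison, 10 for 3 against 3 and 100 drawn for the reversal. Random lists matched on exon length and mean expression, 10000 for each list tested, drew each member from its 100 nearest genes. No library was left out of the fit.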

Results

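Liver RNA of mice was sequenced in 9 libraries that fall into 3 groups of 3: wild type, Cth knockout, and Cth knockout with 1% betaine in the drinking water. Cth encodes cystathionine gamma-lyase, which makes cysteine from cystathionine in the transsulfuration pathway and also forms hydrogen sulfide. Betaine donates a methyl group to homocysteine through the liver enzyme Bhmt. The series asks what this enzyme does in chronic liver disease, and its title names histone lysine methylation. The reads recovered from the deposited FPKM came to 16156284, 15428603 and 17473962 in wild type replicates 1 to 3, 15184982, 15765166 and 15545388 in the knockout and 17001535, 16344012 and 15844508 in the betaine group. At that depth 3 reads in a 1 kb transcript equal 0.162 to 0.222 FPKM, counting error only. Of 54532 genes listed, 29112 stood at 0 in every library and 11852 were tested. Log2 fold changes are given ± SE of the fit over 9 libraries, with n = 3 libraries per group, and FPKM as mean ± SD (n = 3).

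Wild type replicate 3 stood apart from the other 8 libraries in sex-linked transcripts. Xist, the RNA that silences an X chromosome in females, measured 26.6 FPKM there and at most 0.0124 FPKM in each other library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in that library and 1512 to 2393 reads together in each of the others. The male urinary protein gene Mup20 measured 55.4 FPKM there against 1991 to 4724 FPKM elsewhere, and the female-biased Cyp2b9 measured 215 FPKM against 0 to 37.3 FPKM. The labels give no sex. Cth itself measured 219 FPKM in this library, against 285.4 and 256.6 FPKM in the other wild type ones. Values without wild type replicate 3 are therefore given beside several of the gene groups that moved with it.

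**Figure D1:**
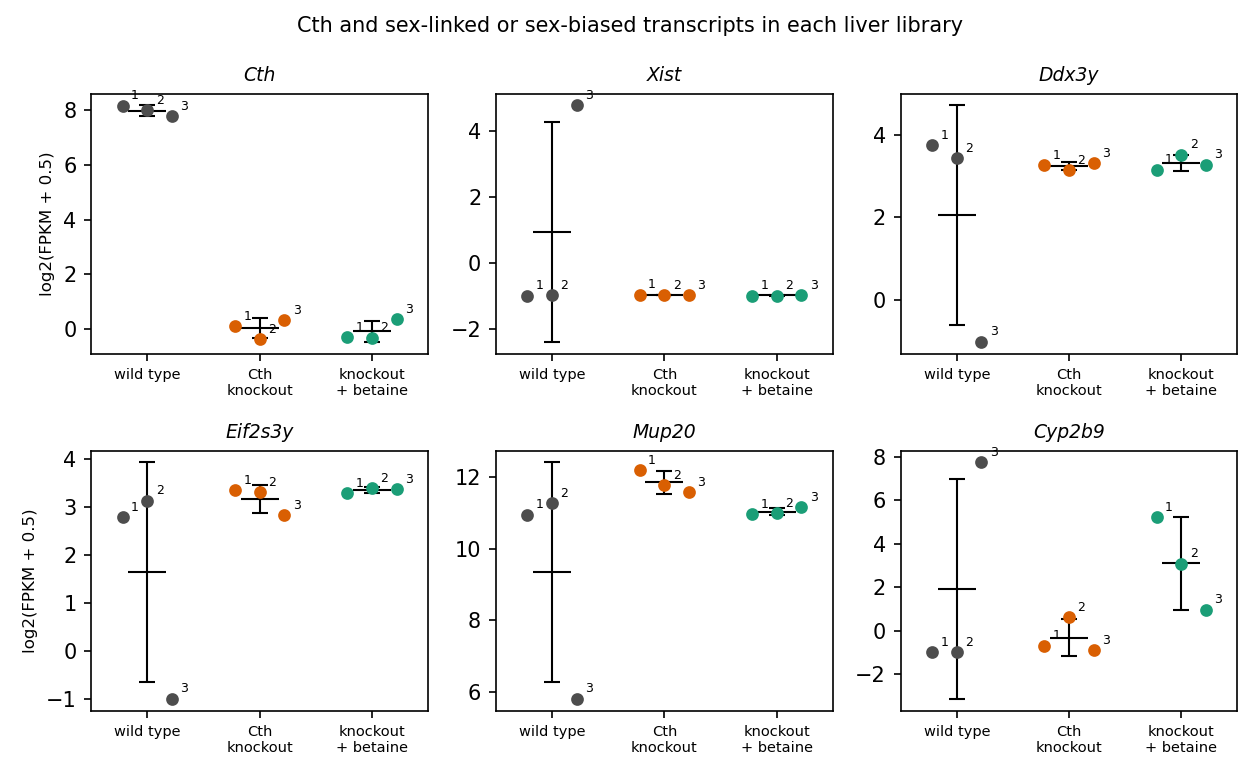
Cth and 5 sex-linked or sex-biased transcripts as log2(FPKM + 0.5) in each of 9 liver libraries by group; points carry the replicate number, and bars give the mean ± SD (n = 3). Wild type replicate 3 has Cth at 219 FPKM with Xist at 26.6 FPKM and no Ddx3y or Eif2s3y.

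The comparison of the Cth knockout with wild type asked which liver transcripts differ when the enzyme is missing. Cth (ENSMUSG00000028179, chromosome 3, bases 157894248 to 157925077 of GRCm38, a protein-coding gene) fell from 254 ± 33.3 FPKM in wild type to 0.544 ± 0.248 FPKM in the knockout, a log2 fold change of -7.95 ± 0.23 (adjusted p = 3.36e-07). Bhmt, which uses betaine to remethylate homocysteine, rose from 453 ± 67.5 to 1139 ± 106 FPKM, by 1.34 ± 0.19. Ppara, the nuclear receptor that drives fatty acid oxidation genes, fell from 25.99 ± 5.31 to 5.02 ± 1.159 FPKM. Herpud1, a gene of endoplasmic reticulum protein degradation, fell from 304 ± 41.8 to 119 ± 8.51 FPKM. Transcripts of mitochondrial respiration and of ribosomes rose as groups, and those of histone lysine demethylases fell as a group, under the set test with a preset correlation. With an estimated correlation these calls were lost, with adjusted p of 0.977, 0.977 and 0.973, and with the exon length trend removed the demethylase list gave adjusted p = 0.0826.

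In the limma fit 3029 genes changed, 1519 higher and 1510 lower in the knockout, and 4742 had an unadjusted p under 0.05. Without wild type replicate 3 the count was 2559, of which 2169 were among the 3029. The count was 1808 without wild type replicate 1, and 1950, 897 and 1707 without knockout replicates 1, 2 and 3 in turn. Rescaled to TPM, where the median of all genes shifted by -0.32, 4218 genes changed and 13.8% of them were higher, against 50.1% in FPKM. On each library's own read total 3121 changed and 37.5% were higher. Of the 111 genes that the naming rule gave for this comparison and that passed the threshold, 50 stayed past it whichever single library was left out. The number that stayed was 51 without knockout replicate 2, 85 without knockout replicate 3, 86 without knockout replicate 1, 87 without wild type replicate 1 and 100 or more without any other library.

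The largest rises by the naming rule included Mup16 (2.61 ± 0.34), Mup9 (2.77 ± 0.60) and Mup11 (3.98 ± 1.20), major urinary protein genes with higher levels in males, and Sult2a7 (3.32 ± 0.98), a sulfotransferase gene. Their values were 2.49, 2.03, 2.44 and 3.67 without wild type replicate 3. Fitm1, a lipid droplet gene, rose by 2.77 ± 0.86, and by 1.61 without that library. Cenpm (2.47 ± 0.22), the precursor of the liver microRNA, Mir122 (2.496 ± 0.64), and the mitochondrial transfer RNA gene mt-Tv completed the 8. mt-Tv had 1 read in the 3 wild type libraries and 12 in the knockout, too few to size its change. These 8 genes had adjusted p 0.00447 to 0.0482. Over the 9 fits with 1 library left out, the calls of Mup11 and Fitm1 were kept in 2 and that of Sult2a7 in 3. Mir122 was kept in 6, Mup9 in 8, and Mup16, Cenpm and mt-Tv in 9. Beside Cth, the largest falls were in Gpam (-2.72 ± 0.54), which starts glycerolipid synthesis, Pdpr (-2.56 ± 0.35), a regulator of pyruvate dehydrogenase phosphatase, Acnat2 (-2.52 ± 0.54), Rnf125 (-2.49 ± 0.47), Ppara (-2.26 ± 0.29), Ptp4a1 (-2.19 ± 0.44) and Sacm1l (-2.18 ± 0.36), with adjusted p 0.00546 to 0.0137. Reads of near-identical copies, as in the Mup, Sult2a, Cyp, Gstm, Orm and Serpina1 families, between mitochondrial genes and their nuclear copies, or of overlapping genes on opposite strands can be counted for one another, so values of single members are uncertain.

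In the methionine cycle and transsulfuration list 5 members rose and 2 fell of 27 measured, and the counts were the same adjusted over the list alone. Bhmt (1.34 ± 0.19), Gamt (1.12 ± 0.19), which makes creatine with a methyl group from S-adenosylmethionine, Mpst (0.85 ± 0.17) and Tst (0.75 ± 0.12), both enzymes of sulfur transfer, rose with adjusted p 0.00567 to 0.0104. The list's median of 0.008 had the opposite sign to its mean of -0.015 and to its test (adjusted p = 0.981). In folate one-carbon metabolism Gldc (-0.54 ± 0.14), Slc25a32 (-0.93 ± 0.27) and Gart (-0.56 ± 0.17) fell, 3 of 20 measured, and 0 passed limma adjusted over the list alone, with 5 at an unadjusted p under 0.05. In choline and phosphatidylcholine metabolism Pcyt1a (-1.35 ± 0.23), the regulated step of phosphatidylcholine synthesis from choline, Etnk1 (-1.15 ± 0.18) and the choline transporter Slc44a1 (-0.43 ± 0.13) fell, and Pla2g6 (0.60 ± 0.18) rose, with adjusted p 0.00630 to 0.0427. That made 1 higher and 3 lower of 17, also adjusted over the list alone. The tests of the folate and choline lists gave adjusted p = 0.855 and 0.720.

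Among glutathione synthesis and NRF2 targets 7 members rose and 1 fell of 26, the same counts adjusted over the list alone. Taldo1 (0.82 ± 0.15), Gstm2 (0.97 ± 0.18) and Gstm6 (1.07 ± 0.19), the last 2 glutathione transferases, rose, and the efflux transporter Abcc3 (-0.84 ± 0.17) fell, with adjusted p 0.00742 to 0.0103. The list as a whole gave adjusted p = 0.0909. In the ATF4 and amino acid response list Nupr1 (0.72 ± 0.18) rose and Sesn2 (-0.89 ± 0.21) and Slc7a5 (-0.67 ± 0.20) fell of 20 measured, and 1 rose and 1 fell adjusted over the list alone. Among endoplasmic reticulum chaperones 2 rose and 5 fell of 21, and 2 rose and 6 fell adjusted over the list alone. Herpud1 (-1.34 ± 0.18), Dnajc3 (-0.95 ± 0.16) and Sel1l (-0.77 ± 0.15) fell and the translocon subunit Sec61b (1.163 ± 0.18) rose, with adjusted p 0.00556 to 0.00878. The last 2 lists gave adjusted p = 0.981 and 0.393.

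Members of the cholesterol synthesis list went both ways, 3 higher and 2 lower of 25, also adjusted over the list alone. Stard4 (-0.72 ± 0.20) fell, and Ebp (0.74 ± 0.15) and Nsdhl (1.23 ± 0.33) rose, with adjusted p up to 0.0278. The median of 0.032 differed in sign from the mean of -0.16 and from the test (adjusted p = 0.877), and without wild type replicate 3 the median was 0.31 with a positive test (adjusted p = 0.486). In fatty acid and triglyceride synthesis Gpam (-2.72 ± 0.54), Scd1 (-1.70 ± 0.42) and Fads2 (-0.99 ± 0.14), which are a glycerolipid enzyme and a pair of desaturases, fell and Agpat2 (0.64 ± 0.14) rose, with adjusted p 0.00567 to 0.0201. There 1 rose and 4 fell of 21, the same adjusted over the list alone (median -0.33, adjusted p = 0.293), and the median was 0.010 (adjusted p = 0.962) without wild type replicate 3. Of 33 fatty acid oxidation and PPAR-alpha targets 5 rose and 5 fell, and 8 rose and 6 fell adjusted over the list alone (list adjusted p = 0.855). Fabp1 (1.60 ± 0.23), the liver fatty acid binding protein, and Vnn1 (1.21 ± 0.26) rose while Cpt1a (-0.90 ± 0.13) fell, with adjusted p 0.00567 to 0.0130.

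Bile acid genes Slco1b2 (-0.92 ± 0.19), Abcc2 (-0.87 ± 0.22), Cyp27a1 (-0.52 ± 0.12) and Slc27a5 (-0.57 ± 0.15) fell, 4 of 20 measured and 4 adjusted over the list alone. In glucose metabolism Irs1 (-1.11 ± 0.27), Foxo1 (-1.09 ± 0.34) and Fbp1 (-0.52 ± 0.16) fell and Gpi1 (0.73 ± 0.18) rose of 21, and 1 rose and 1 fell adjusted over the list alone. Among xenobiotic cytochrome P450s 3 rose and 2 fell of 24, also adjusted over the list alone, with Cyp1a2 (1.03 ± 0.16) and Cyp2a12 (0.79 ± 0.15) higher and Cyp2c29 (-1.75 ± 0.25) and Cyp3a13 (-0.88 ± 0.18) lower. Amino acid catabolism and urea cycle genes had 3 higher and 3 lower of 30, and 2 higher and 3 lower adjusted over the list alone. There Cps1 (-1.42 ± 0.31), the entry step of the urea cycle, Tdo2 (-1.06 ± 0.23) and Slc25a13 (-0.70 ± 0.17) fell and Fah (0.75 ± 0.18) rose. The lists gave adjusted p = 0.567 for bile acids, 0.394 for glucose, 0.877 for the P450s and 0.855 for amino acids. The P450 median of 0.054 and test were positive and its mean of -0.14 negative, and the amino acid median of 0.047 was positive with a mean of -0.11 and a negative test.

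Of 30 genes of hepatocyte secreted proteins and identity 8 rose and 4 fell, and 9 rose and 4 fell adjusted over the list alone (list adjusted p = 0.298). Foxa2 (1.19 ± 0.28) and Serpina1c (1.32 ± 0.32) rose, and the liver transcription factor Hnf4a (-0.66 ± 0.15) and Apob (-1.06 ± 0.20), the protein of very low density lipoprotein, fell. Pericentral genes had 3 higher and 1 lower of 14, with Lect2 (0.85 ± 0.21) and Rhbg (0.79 ± 0.21) higher and Slc1a2 (-0.52 ± 0.13) lower, and periportal genes 2 lower of 14, Ctsc (-1.05 ± 0.24) and Gldc (-0.54 ± 0.14). Both pairs of counts were the same adjusted over the list alone, and the lists gave adjusted p = 0.454 and 0.346. Among 26 acute phase proteins Orm1 (1.05 ± 0.18) and Orm2 (1.30 ± 0.23) rose and 3 fell, Itih4 (-1.08 ± 0.23) and Cp (-0.44 ± 0.12) among them, with 2 higher and 2 lower adjusted over the list alone. The acute phase median of -0.13 was negative while the mean of 0.13 and the test were positive (adjusted p = 0.981), and without wild type replicate 3 the median was 0.25 (adjusted p = 0.631).

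Interferon-stimulated genes had 8 higher and 0 lower of 28, also adjusted over the list alone, among them Isg15 (1.21 ± 0.27), Ifit3 (0.89 ± 0.19) and Irf7 (0.59 ± 0.15), with adjusted p 0.0117 to 0.0189. The list gave adjusted p = 0.0579, and 0.977 with an estimated correlation, over all 9 libraries. Without wild type replicate 3 it gave adjusted p = 0.000666 with a median of 0.54, and there the estimated correlation was not run. In the inflammatory cytokine list Myd88 (0.43 ± 0.12) rose, 1 of 17, and 0 passed adjusted over the list alone (limma, 4 at an unadjusted p under 0.05). Among p53 targets and apoptosis genes Bax (0.93 ± 0.18) rose and Perp (-0.69 ± 0.14) and Trp53inp1 (-2.00 ± 0.58) fell, 1 higher and 5 lower of 16, also adjusted over the list alone. The last 2 lists gave adjusted p = 0.454 and 0.142. The median of stellate cell and matrix genes, the collagen and contractile genes of liver fibrosis, was 0.17 over all 9 libraries. The list gave adjusted p = 0.664, and 0.988 with an estimated correlation. Without wild type replicate 3 the median was 0.39 (adjusted p = 0.0206), and there the estimated correlation was not run.

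Nuclear oxidative phosphorylation subunits had 25 higher and 0 lower of 36, and 28 higher and 1 lower adjusted over the list alone. Their median was 0.76 (adjusted p = 4.69e-08, and adjusted p = 0.977 with an estimated correlation), positive under each scaling tried, between 0.34 and 0.75. Ndufv2 (0.95 ± 0.14), Ndufa5 (1.53 ± 0.24), Ndufb3 (1.48 ± 0.24) and Ndufa8 (1.13 ± 0.20), subunits of respiratory complex I, rose with adjusted p 0.00567 to 0.00780. Ribosomal protein genes had 22 higher and 0 lower of 34, and 24 higher adjusted over the list alone, with a median of 0.64 (adjusted p = 4.69e-08, and adjusted p = 0.977 with an estimated correlation), between 0.22 and 0.63 over the scalings. Rpl32 (1.00 ± 0.18), Rpl27 (1.05 ± 0.21) and Rps2 (0.87 ± 0.18) were among them. Of 13 mitochondrially encoded transcripts 8 rose and 9 rose adjusted over the list alone, mt-Nd1 (1.01 ± 0.19), mt-Nd5 (0.98 ± 0.20) and mt-Co1 (1.01 ± 0.22) included. Their median was 1.00 (adjusted p = 0.000727, and adjusted p = 0.977 with an estimated correlation), between 0.22 and 0.99 over the scalings. Under quantile normalization that call was lost (adjusted p = 0.190), and the other 2 stayed (0.000138 and 0.000861). The list means of the 3 knockout libraries were 0.58 to 0.76 for the nuclear subunits, 0.45 to 0.66 for ribosomal proteins and 0.66 to 1.11 for mitochondrial transcripts, each above all 3 wild type libraries. Without wild type replicate 3 the medians of these lists were 0.58, 0.51 and 1.01 in that order. The genes called were then 17 higher and 1 lower, 16 higher and 0 lower, and 8 higher and 0 lower.

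Transcripts with short exon length were higher and those with long exon length lower in the knockout. The Spearman correlation across genes of the log2 fold change with exon length was -0.461, and genes are not independent replicates. In the shortest 3950 genes, up to 2677 bases, the median was 0.35, with 950 higher and 111 lower, and in the longest 3949 genes, over 5244 bases, it was -0.25, with 152 higher and 957 lower. With each library's length trend removed the medians were smaller, 0.43 for nuclear oxidative phosphorylation (adjusted p = 4.85e-06), 0.39 for ribosomal proteins (adjusted p = 2.00e-05) and 0.49 for mitochondrial transcripts (adjusted p = 0.0302), with 15, 14 and 5 genes higher. With wild type replicate 3 left out as well, the medians were 0.32, 0.285 and 0.607 in that order (camera adjusted p = 0.000809, 0.000892 and 0.00598).

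**Figure D2:**
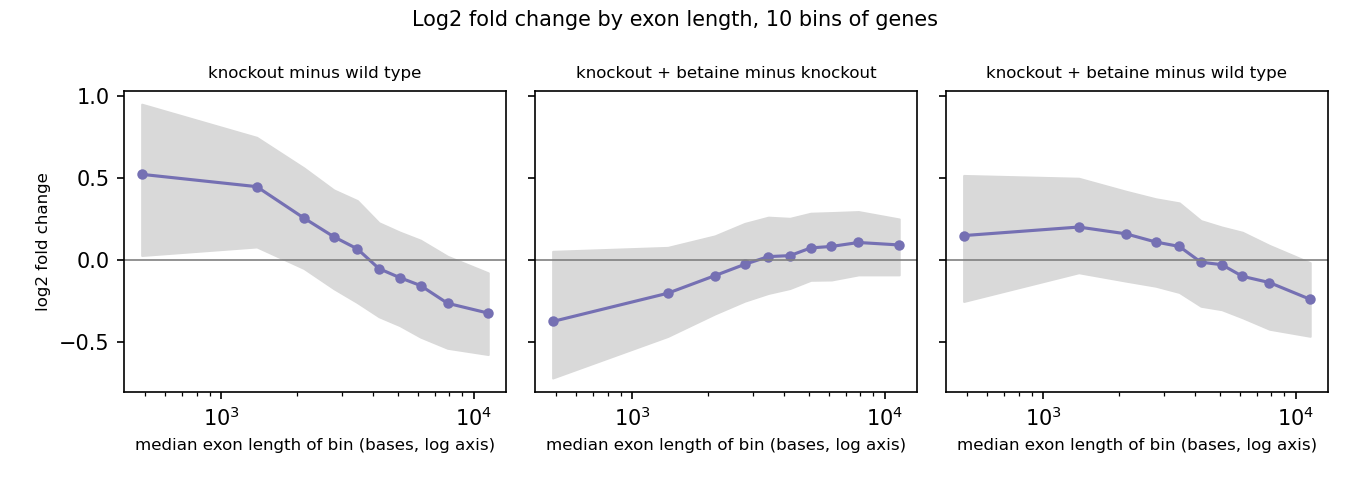
Median log2 fold change (line) and quartiles (shaded) in 10 bins of genes against exon length in bases on a log axis, for each of the 3 comparisons. Knockout minus wild type runs from 0.52 in the shortest bin to -0.32 in the longest, and betaine minus knockout from -0.37 to 0.092.

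Histone lysine demethylase transcripts, whose products remove the marks named in the series title, had 5 lower and 0 higher of 19, and 7 lower adjusted over the list alone. Kdm5c (-0.72 ± 0.13), Kdm2a (-0.82 ± 0.18), Kdm7a (-0.72 ± 0.17) and Kdm5a (-0.69 ± 0.18) fell, with adjusted p 0.00801 to 0.0229. The list median was -0.34 (adjusted p = 0.00165, and adjusted p = 0.973 with an estimated correlation) and negative under each scaling tried. Among the methyltransferases that write those marks 6 fell and 0 rose of 30, also adjusted over the list alone, Ash1l (-0.95 ± 0.15), Setd2 (-0.69 ± 0.12), Setdb2 (-1.27 ± 0.27) and Kmt2e (-0.59 ± 0.15) among them. Their median was -0.20 (adjusted p = 0.0471, and adjusted p = 0.973 with an estimated correlation), also negative under each scaling. With the length trend removed the demethylase list gave adjusted p = 0.0826 and the methyltransferase list 0.968, and members of both lists have long exons, with medians of 7110 and 7778 bases. The methyltransferase call was also lost without wild type replicate 2, knockout replicate 1 or betaine replicates 1 or 2, with adjusted p up to 0.130.

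Male-biased liver genes were higher and female-biased ones lower in the knockout as groups, with medians of 1.86 and -1.82 (adjusted p = 0.0443 for both, and adjusted p = 0.977 with an estimated correlation). Without wild type replicate 3 the medians were 0.47 (adjusted p = 0.172) and 0.18 (adjusted p = 0.945), the latter over the 4 of 16 female-biased genes that then passed the filter and so not comparable with the median of 16. Both calls were also lost without knockout replicate 1 or betaine replicates 1 or 2. Among the male-biased genes Cyp2u1 (1.76 ± 0.54) rose, 1 of 18, and 0 passed adjusted over the list alone, while Mup21 (4.01 ± 1.30) had adjusted p = 0.0564. Without wild type replicate 3, 4 of the 18 male-biased genes were higher and 0 lower over all genes tested. Of 16 female-biased genes 0 passed limma either way, 1 at an unadjusted p under 0.05, and Fmo2 (-1.36 ± 0.48) had adjusted p = 0.0656. The sex-chromosome genes, Uty (0.71 ± 0.43) and Eif2s3y (1.52 ± 0.95) among them, had 0 called of 5 (limma, 0 at an unadjusted p under 0.05), with a median of 0.71 and 0.085 without wild type replicate 3. Sinusoidal endothelial markers had a median of -0.58 (adjusted p = 0.0163, and adjusted p = 0.977 with an estimated correlation), with Kdr (-0.80 ± 0.25) lower, 1 of 17, and 0 adjusted over the list alone. Leaving out wild type replicate 3, that median was -0.30 (adjusted p = 0.366). Circadian clock genes had 4 lower and 0 higher of 16, also adjusted over the list alone, and a median of -0.55 (adjusted p = 0.0443, and adjusted p = 0.973 with an estimated correlation). Clock (-0.62 ± 0.17), Arntl (-0.54 ± 0.15), Rora (-0.94 ± 0.17) and Nfil3 (-0.86 ± 0.15) fell. With the exon length trend removed the clock list gave adjusted p = 0.148. The clock call was also lost without wild type replicate 3, knockout replicates 1 or 2 or betaine replicates 1 or 2, with adjusted p up to 0.110. Under quantile normalization the male-biased, female-biased, endothelial, clock and methyltransferase calls were lost, with adjusted p of 0.0778, 0.0586, 0.0531, 0.0682 and 0.121, and in TPM the female-biased, endothelial and clock calls, with 0.712, 0.125 and 0.164. On own read totals the female-biased and clock calls were lost as well (adjusted p = 0.137 and 0.0640).

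Apart from the endothelial markers above, markers of other cell types had no gene past the threshold in the knockout with all 9 libraries. This was so over all genes tested and adjusted over the list alone. That held in limma for macrophage and Kupffer cell markers (18 measured, 3 at an unadjusted p under 0.05), lymphocyte markers (9, 2), stellate cell and matrix genes (27, 2), cholangiocyte and ductular markers (6, 1), red blood cell markers (5, 0), cell cycle genes (12, 0) and immediate-early and heat shock genes (15, 2). Without wild type replicate 3, 4 of 26 stellate cell and matrix genes were higher and 0 lower. With the exon length trend also removed their median was 0.525 (camera adjusted p = 0.00152). Lymphocyte markers had 1 higher without that library, and the cholangiocyte and immediate-early lists 1 lower each. With the exon length trend removed the macrophage and Kupffer list had a median of -0.48 (adjusted p = 0.0306), and -0.18 (adjusted p = 0.196) with wild type replicate 3 left out as well. With an estimated correlation and no such correction it gave adjusted p = 0.988. The list tests in the fit without that correction gave adjusted p = 0.346, 0.855, 0.664, 0.966, 0.855, 0.798 and 0.293 in that order. Kupffer cell markers Adgre1 (-1.70 ± 0.55) and Cd5l (-0.95 ± 0.38), the lymphocyte gene Trac (-0.74 ± 0.31), the duct marker Sox9 (-0.87 ± 0.29), the globin Hbb-bs (-0.92 ± 0.93) and Ccnd1 (-1.27 ± 0.72) had adjusted p of 0.0525, 0.0945, 0.110, 0.0535, 0.488 and 0.218. Neutrophil markers, with S100a8 (0.25 ± 0.48), and pancreas, adipose and muscle markers, with Fabp4 (0.47 ± 0.19), had 3 measured genes each, too few for the list test, and 0 called (limma, 0 and 1 at an unadjusted p under 0.05).

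**Figure D3:**
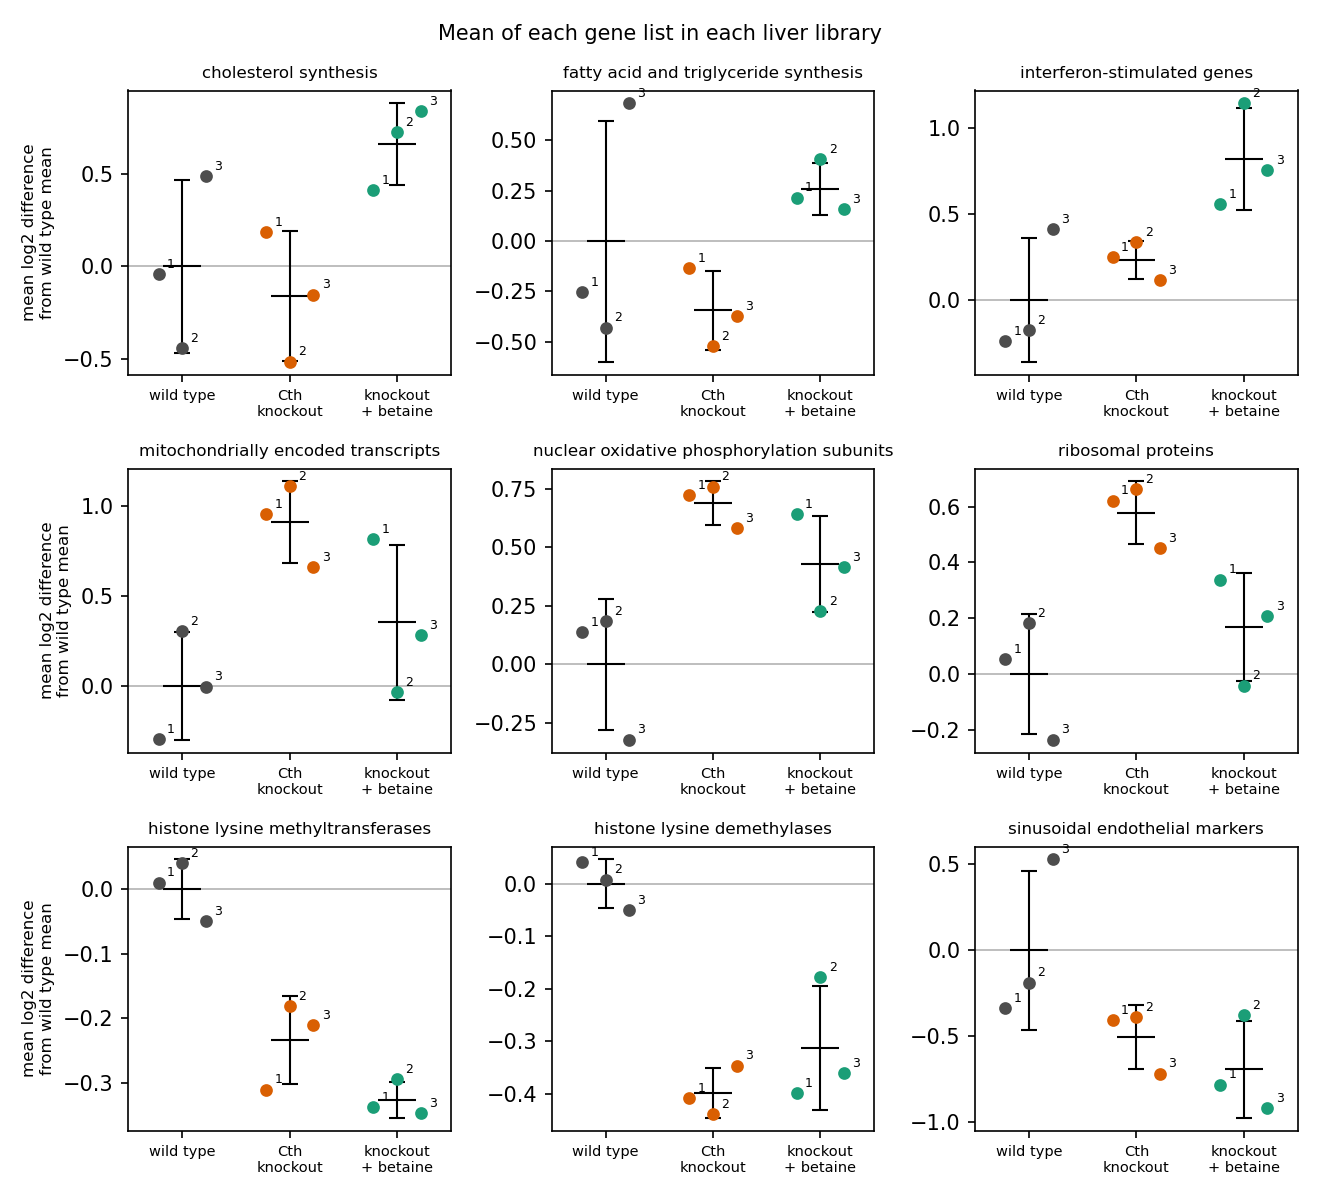
Mean log2 difference from the wild type mean over 9 gene lists in each of 9 liver libraries; points carry the replicate number, and bars give the mean ± SD (n = 3). The 3 knockout libraries lie above all wild type libraries for nuclear oxidative phosphorylation subunits, at 0.58 to 0.76, and the 3 betaine libraries lie above all knockout libraries for interferon-stimulated genes, at 0.56 to 1.14.

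The comparison of the betaine-supplemented knockout with the untreated knockout asked which transcripts differ when betaine is supplied without the enzyme. Oasl1, an interferon-stimulated gene, rose from 3.88 ± 0.175 FPKM in the knockout to 13.4 ± 3.71 FPKM with betaine, by 1.62 ± 0.18, and Bbc3, which encodes a pro-apoptotic protein, rose from 4.02 ± 0.841 to 11.4 ± 2.34 FPKM, by 1.40 ± 0.17 (adjusted p = 0.0391 for both, higher in 3 of 3 betaine libraries). Genes of cholesterol synthesis, of fatty acid and triglyceride synthesis and of the interferon response were higher as groups, and those of ribosomes and of mitochondrial transcripts lower, under the set test with a preset correlation. With an estimated correlation all 5 calls were lost (camera adjusted p = 0.945 each, unadjusted p from 0.139 to 0.202). Cth stood at 0.544 ± 0.248 FPKM without and 0.470 ± 0.269 FPKM with betaine. Bhmt measured 1139 ± 106 and 1712 ± 382 FPKM in the same order (log2 fold change 0.57 ± 0.19, adjusted p = 0.142).

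In the limma fit 5 genes changed, 2 higher and 3 lower, and 2672 had an unadjusted p under 0.05. The 3 lower ones, which the naming rule takes only as reversals, were the pseudogene Gm12276, with 78 reads in the knockout and 25 with betaine, the transfer RNA mt-Tv, with 12 and 0 reads, and the small nuclear RNA Gm26271, with 14 and 0 reads (adjusted p = 0.0391 each). The count was 273 without wild type replicate 3, 882 without betaine replicate 1, 1 without wild type replicate 1 or betaine replicate 2 and 0 without knockout replicates 2 or 3 (limma, 1521 and 1993 at an unadjusted p under 0.05). None of the 5 calls was kept under every left-out library. In TPM, where the median of all genes shifted by 0.30, 1673 genes changed and 95.6% were higher, against 40.0% in FPKM, and on own read totals 67 changed with 80.6% higher.

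Cholesterol synthesis genes had a median of 0.83 (adjusted p = 3.89e-08, and adjusted p = 0.945 with an estimated correlation), with 22 of 25 above 0. Over all genes 0 passed limma (18 at an unadjusted p under 0.05) and 16 were higher adjusted over the list alone. Mvk (1.14 ± 0.23) and, in the fatty acid and triglyceride list, Srebf1 (1.35 ± 0.21), the transcription factor of lipid synthesis, and Fads2 (0.80 ± 0.14) had adjusted p 0.0608 to 0.0837. The fatty acid and triglyceride list had a median of 0.68 (adjusted p = 0.000742, and adjusted p = 0.945 with an estimated correlation), 0 of 21 called (limma, 9 at an unadjusted p under 0.05) and 8 higher adjusted over the list alone. Interferon-stimulated genes had a median of 0.68 (adjusted p = 3.40e-06, and adjusted p = 0.945 with an estimated correlation), 1 called of 28 and 9 higher adjusted over the list alone. Ifit3 (1.06 ± 0.19) had adjusted p = 0.0758. These 3 medians were positive under each scaling tried, and the list means of the betaine libraries, 0.41 to 0.84, 0.16 to 0.41 and 0.56 to 1.14, lay above those of all 3 knockout libraries. The calls of single members depended on the libraries kept. Without wild type replicate 3, which is in neither group compared, 6, 5 and 5 members of these lists were higher over all genes and 0 lower. Without knockout replicates 2 or 3, 0 genes of any kind passed.

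Ribosomal protein genes had a median of -0.49 (adjusted p = 3.00e-08), mitochondrially encoded transcripts -0.72 (adjusted p = 0.000742) and nuclear oxidative phosphorylation subunits -0.32 (adjusted p = 0.00402). All 3 gave adjusted p = 0.945 with an estimated correlation. The log2 fold change was higher in genes with longer exons here, at a Spearman correlation of 0.285 across genes, which are not independent replicates, and with that trend removed the 3 lists gave adjusted p = 1.91e-07, 0.0182 and 0.0789, so the call of the last was lost. The list means of the betaine libraries were -0.042 to 0.34, -0.037 to 0.82 and 0.23 to 0.64. The first lay below all 3 knockout libraries, and in the other 2 lists betaine replicate 1 lay above knockout replicate 3. Adjusted over the list alone 10 of 34, 8 of 13 and 0 of 36 were lower, and over all genes 0 passed limma (20, 8 and 12 at an unadjusted p under 0.05). Rpl27 (-0.74 ± 0.21), mt-Nd2 (-0.93 ± 0.22) and Ndufa5 (-0.73 ± 0.24) had adjusted p 0.0886 to 0.133. Hepatocyte secreted protein and identity genes, with Trf (-1.15 ± 0.31) for transferrin and Foxa3 (-0.72 ± 0.20), had a median of -0.35 (adjusted p = 0.000105, and adjusted p = 0.945 with an estimated correlation). Fatty acid oxidation and PPAR-alpha targets, with Angptl4 (-2.53 ± 0.55) and Fabp1 (-0.84 ± 0.23), had a median of -0.21 (adjusted p = 0.0207, and adjusted p = 0.945 with an estimated correlation). Under quantile normalization the ribosomal call stayed (adjusted p = 3.80e-05) and the mitochondrial, oxidative phosphorylation, hepatocyte and PPAR-alpha calls were lost, with adjusted p of 0.284, 0.284, 0.581 and 0.432. In TPM the oxidative phosphorylation and PPAR-alpha calls were lost as well (adjusted p = 0.178 and 0.0891). The TPM medians of the oxidative phosphorylation, PPAR-alpha and hepatocyte lists were positive, at 0.042, 0.152 and 0.011, where the median of all genes was 0.302. Those of the ribosomal and mitochondrial lists stayed negative, at -0.139 and -0.365. The PPAR-alpha call was also lost without knockout replicate 3 or betaine replicate 3, with adjusted p up to 0.140. In the hepatocyte and PPAR-alpha lists 0 of 30 and 0 of 33 genes passed limma over all genes (11 and 10 at an unadjusted p under 0.05), and 0 and 1 lower adjusted over the list alone.

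In the remaining lists 1 gene, Bbc3 among p53 targets, passed over all genes tested. Adjusted over the list alone, methionine cycle and transsulfuration genes had 6 higher and 1 lower of 27 (median 0.22, adjusted p = 0.160), with Suox (0.50 ± 0.13), amino acid catabolism 3 higher of 30 (median 0.036, adjusted p = 0.731), with Gpt (0.51 ± 0.12) and Prodh (0.59 ± 0.14), and folate one-carbon genes 2 higher of 20 (median 0.070, adjusted p = 0.381), with Atic (0.79 ± 0.15) and Aldh1l1 (0.68 ± 0.18). The p53 list had 2 higher and 1 lower of 16 (median 0.23, adjusted p = 0.214), choline and phosphatidylcholine genes 1 higher of 17 with Pcyt1a (1.07 ± 0.23), periportal genes 1 higher with Hal (0.70 ± 0.16), male-biased genes 1 higher with Ces2e (0.81 ± 0.20), pericentral genes 1 lower with Slc1a2 (-0.63 ± 0.13), inflammatory genes 1 lower with Myd88 (-0.63 ± 0.12) and the ATF4 list 1 lower with Fgf21 (-1.92 ± 0.40), a fasting hormone of liver. Histone methyltransferases had 1 lower of 30 with Prdm2 (-1.03 ± 0.16) (median -0.077, adjusted p = 0.469) and demethylases 1 lower of 19 with Riox1 (-0.78 ± 0.17) (median 0.12, adjusted p = 0.469). The other lists had 0 genes past limma either way, with 0 to 6 members at an unadjusted p under 0.05 and list adjusted p from 0.214 to 0.995, and the glucose list held Pck1 (-1.78 ± 0.53), a gluconeogenic enzyme, at adjusted p = 0.120. Medians differed in sign from the mean or the test for choline, P450, sex-chromosome, pericentral and periportal genes, between -0.030 and 0.051.

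**Figure D4:**
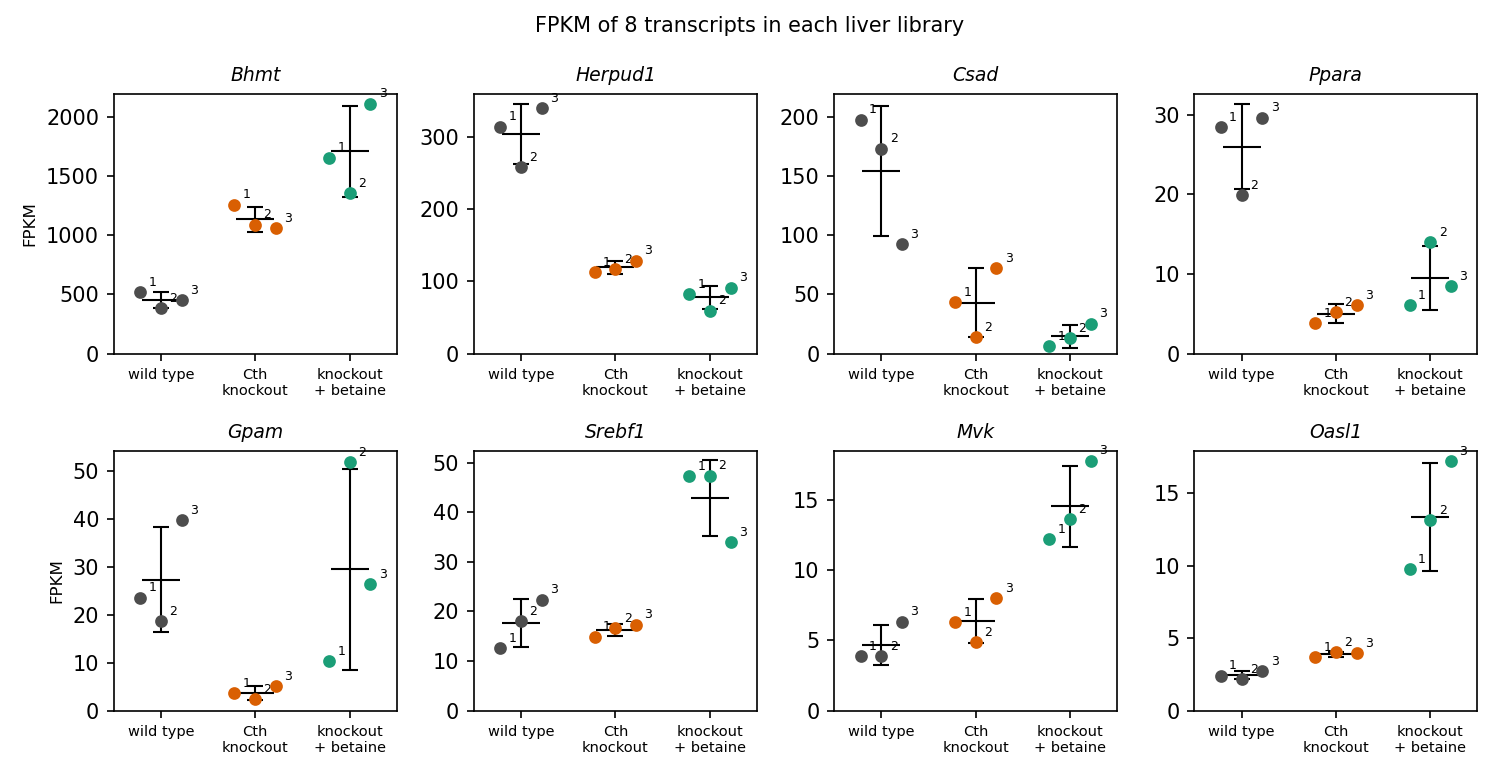
FPKM of Bhmt, Herpud1, Csad, Ppara, Gpam, Srebf1, Mvk and Oasl1 in each of 9 liver libraries by group, on linear axes from 0; points carry the replicate number, and bars give the mean ± SD (n = 3). Bhmt averages 453, 1139 and 1712 FPKM, and Oasl1 2.44, 3.88 and 13.4 FPKM, in wild type, knockout and knockout with betaine.

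Whether betaine moved knockout-changed transcripts back was counted over genes called in both comparisons. With opposite signs there were 3, Gm12276, mt-Tv and Gm26271, all higher in the knockout and lower with betaine, and with the same sign 1, Oasl1 (0.58 ± 0.18 in the knockout and 1.62 ± 0.18 with betaine). Overlap of unrelated calls would give 0.639 genes with opposite and 0.639 with the same sign, leaving aside that both comparisons share the knockout libraries. In simulations that include this, the opposite count averaged 0.02 with no effect and 0.04 with the knockout effect and no betaine effect, at most 1 in each. These 3 genes have exons of 301, 69 and 104 bases, and the trend with exon length ran in opposite directions in the 2 comparisons. With that trend removed 3 genes had opposite signs, 0 of them higher and 3 lower in the knockout, so the 3 named were no longer among them. Of the 3029 genes changed in the knockout, 2570 (84.8%) had the opposite sign with betaine. Both comparisons share the 3 knockout libraries, which alone pushes signs apart: in 50 simulations with the knockout effect and no betaine effect the share was 60.2%, at most 61.4%. These simulations drew genes independently and took the fitted knockout changes as the true ones. They hold neither a trend shared by genes, as with exon length, nor the full selection of called genes on noise. The gap to 84.8% therefore does not separate betaine from these, and the same limit holds for the other simulated values here. The log2 fold changes correlated at -0.566 across genes, which are not independent replicates, against -0.497 (-0.549 to -0.431) in simulations with no effect and -0.208 in those with the knockout effect and no betaine effect, and their covariance was -0.153 against -0.0366 and -0.0375. Without wild type replicate 3 the correlation was -0.525, the covariance -0.135 and the share with opposite signs 82.2%. All simulations held 9 libraries, so they give no matched range for these values. Without wild type replicate 3 the count was 90, with 51 higher and 39 lower in the knockout, and 16 had the same sign. It ranged from 0 to 541 as single libraries were left out.

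The comparison of the betaine-supplemented knockout with wild type asked what still differed with betaine. Cth stood at 0.470 ± 0.269 FPKM, a log2 fold change of -8.06 ± 0.23 (adjusted p = 2.95e-07). Bhmt rose by 1.90 ± 0.19 and Oasl1 by 2.21 ± 0.18. Cd36 (2.13 ± 0.29), a fatty acid transporter, and the nuclear noncoding RNA Neat1 (2.17 ± 0.19) rose, and Csad (-3.48 ± 0.67), which makes the taurine precursor hypotaurine, and Herpud1 (-1.98 ± 0.18) fell. Interferon and cholesterol synthesis genes were higher and sinusoidal endothelial markers lower as groups, under the set test with a preset correlation, and with an estimated correlation these 3 calls were lost (adjusted p = 0.871 each).

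In the limma fit 1381 genes changed, 696 higher and 685 lower, and 3614 had an unadjusted p under 0.05. There were 1417 without wild type replicate 3, of which 1032 were among the 1381. The count was 579 and 639 without wild type replicates 1 and 2, 863 and 913 without knockout replicates 2 and 3, and 631 and 347 without betaine replicates 1 and 3. On own read totals 1515 changed and 69.6% were higher, against 50.4%. Of the 93 genes of the naming rule past the threshold 33 stayed past it whichever library was left out. The number that stayed was 39 without betaine replicate 3, 57 without betaine replicate 1 or wild type replicate 1, 63 without wild type replicate 2, 67 without knockout replicate 2 and 75 to 80 without any other.

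The largest rises included Sult2a7 (4.11 ± 0.98), the acute phase gene Saa1 (3.04 ± 0.80), Cenpm (2.52 ± 0.22), Lad1 (2.19 ± 0.34) and the small nucleolar RNA Snord49a (2.17 ± 0.36), with adjusted p 0.00169 to 0.0471. The largest falls after Cth and Csad were Acnat2 (-3.01 ± 0.54), Gadd45b (-2.48 ± 0.43), the acyl-CoA thioesterase Acot3 (-2.22 ± 0.53), Zbtb16 (-2.20 ± 0.52), Enho (-2.18 ± 0.33) and Pck1 (-2.11 ± 0.53), with adjusted p 0.00840 to 0.0367. Over the 9 fits with 1 library left out, Saa1 was kept in 2, Sult2a7 and Pck1 in 3, Acot3 and Zbtb16 in 4 and Csad in 6. The other rises and falls listed here were kept in 8 or 9. Interferon-stimulated genes had 12 higher and 0 lower of 28, and 13 higher adjusted over the list alone. Ifit1 (1.98 ± 0.28) and Ifit3 (1.95 ± 0.19) rose, and the list median was 0.69 (adjusted p = 1.38e-08, and adjusted p = 0.871 with an estimated correlation). Of 25 cholesterol synthesis genes 9 rose and 11 rose adjusted over the list alone, with a median of 0.58 (adjusted p = 3.00e-05, and adjusted p = 0.871 with an estimated correlation), and 0.88 (adjusted p = 4.59e-09) without wild type replicate 3. Hmgcs1 (1.28 ± 0.21), Mvk (1.55 ± 0.23), Mvd (1.84 ± 0.37) and Fdft1 (1.04 ± 0.21), enzymes of the mevalonate pathway, were among them. Fatty acid and triglyceride synthesis had 3 higher of 21, Srebf1 (1.27 ± 0.21), Acss2 (1.32 ± 0.30) and Agpat2 (0.62 ± 0.14), and 4 adjusted over the list alone (median 0.15, adjusted p = 0.277). Over all 9 libraries that list gave adjusted p = 0.891 with an estimated correlation. Without wild type replicate 3 it had a median of 0.28 with adjusted p = 0.00111, and there the estimated correlation was not run.

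Glutathione synthesis and NRF2 targets had 7 higher and 0 lower of 26, and 10 higher adjusted over the list alone, with Gstm2 (1.26 ± 0.18), Gstm4 (1.03 ± 0.15), Pgd (1.09 ± 0.17) and Gsta2 (1.60 ± 0.31) among them. The median was 0.34 (adjusted p = 0.00724, adjusted p = 0.871 with an estimated correlation and 0.0819 without wild type replicate 3). Nuclear oxidative phosphorylation subunits had 3 higher of 36, 2 adjusted over the list alone, and a median of 0.40 (adjusted p = 1.36e-06, and adjusted p = 0.871 with an estimated correlation), Ndufb3 (1.09 ± 0.24) included. Their median was 0.24 (adjusted p = 0.000798) without wild type replicate 3, with 1 gene higher. Sinusoidal endothelial markers had 3 lower of 17, Tie1 (-0.83 ± 0.20), Fcgr2b (-0.93 ± 0.23) and Clec4g (-0.55 ± 0.15), and 6 lower adjusted over the list alone, with a median of -0.72 (adjusted p = 2.76e-05, and adjusted p = 0.871 with an estimated correlation), and -0.48 (adjusted p = 0.00377) without wild type replicate 3. Histone methyltransferases had 1 higher and 5 lower of 30, 1 and 7 adjusted over the list alone, and a median of -0.34 (adjusted p = 0.000356, and adjusted p = 0.536 with an estimated correlation). Prdm2 (-1.02 ± 0.16), Ash1l (-0.77 ± 0.15), Setd2 (-0.61 ± 0.12) and Kmt2e (-0.69 ± 0.15) fell. Demethylases had 2 lower of 19, Riox1 (-0.93 ± 0.17) and Kdm3a (-0.57 ± 0.16), and 7 lower adjusted over the list alone, with a median of -0.21 (adjusted p = 0.00374, and adjusted p = 0.871 with an estimated correlation). Over the 9 fits with 1 library left out, the Riox1 call was kept in 9 and the Kdm3a call in 0. The log2 fold change again fell with exon length, at a Spearman correlation of -0.302 across genes, which are not independent replicates, and with that trend removed the 2 histone lists gave adjusted p = 0.0606 and 0.101 and the glutathione list 0.0504. These list directions held under each scaling tried.

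Male- and female-biased genes had medians of 1.45 and -1.71 (adjusted p = 0.0431 each, and adjusted p = 0.891 with an estimated correlation). Without wild type replicate 3 the medians were -0.078 and 0.77 (adjusted p = 0.674 and 0.525), with 4 of 16 female-biased genes left to test. In that fit 2 of 18 male-biased genes were higher and 0 lower, and 1 female-biased gene was higher and 1 lower. The list calls were also lost under quantile normalization (adjusted p = 0.0513 each), on own read totals for the male-biased list (0.0918), in TPM for the female-biased list (0.0613) and without betaine replicates 2 or 3. In methionine cycle and transsulfuration genes 7 rose and 2 fell of 27, with 8 and 2 adjusted over the list alone (median 0.10, adjusted p = 0.241), Mpst (1.14 ± 0.17) and Gamt (0.96 ± 0.19) among those higher. Fatty acid oxidation and PPAR-alpha targets had 6 lower of 33, Cpt1a (-1.12 ± 0.13), Ppara (-1.46 ± 0.29) and Acot4 (-1.21 ± 0.24) among them, and 3 higher and 6 lower adjusted over the list alone (median -0.059, adjusted p = 0.241). Circadian clock genes had 2 higher and 5 lower of 16, and 2 and 6 adjusted over the list alone (median -0.44, adjusted p = 0.0786), with Per1 (-2.10 ± 0.50), Nr1d2 (-1.16 ± 0.25), Rora (-0.81 ± 0.17) and Nfil3 (-0.90 ± 0.15). The remaining 24 lists tested had adjusted p from 0.0751 to 0.897. In them Aldh1l1 (0.88 ± 0.18) of folate metabolism, Cyp2a5 (1.38 ± 0.26) and Cyp1a2 (0.90 ± 0.16) of the P450s and Orm2 (1.87 ± 0.23) of the acute phase rose, and Fgf21 (-1.61 ± 0.40), Dnajc3 (-0.80 ± 0.16), Foxa3 (-1.38 ± 0.20), Hnf4a (-0.97 ± 0.15) and Slc1a2 (-1.14 ± 0.13) fell. Stellate cell and matrix genes had 0 called of 27 (limma, 4 at an unadjusted p under 0.05) and a median of 0.29. Over all 9 libraries the list gave adjusted p = 0.918 with an estimated correlation. Without wild type replicate 3, 3 of 26 were higher and 0 lower, with a median of 0.56 (adjusted p = 0.000901), and there the estimated correlation was not run. Median and mean differed in sign for choline, P450, amino acid, acute phase and inflammatory genes, with medians from -0.26 to 0.079.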

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

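Removal of the length trend, alone or with GC content or with wild type replicate 3 left out, and scaling to own read totals were chosen only after the results were seen, and the other alternatives were planned. The result Cth, Cth knockout against wild type kept its direction and its side of the threshold under every alternative, between -8.70 (pseudocount 0.1) and -7.37 (pseudocount 1), and between -8.11 and -7.75 as single libraries were left out. Over all alternatives 6918 values of named genes kept their side of the threshold, 864 fell short of it, 236 passed it and 0 turned. For gene lists these numbers were 2601, 122, 50 and 2. A change of sign was counted as a turn only where the value passed the threshold in the main fit or in the alternative. Values short of it in both could change sign and still be counted as kept. Of the values that sum up a comparison, 135 stayed within 1.5 times (for Cth, kept sign and side of the threshold) and 62 did not. The replicate numbers did not pair the libraries, since deviations from the group mean correlated at -0.227 to 0.098 between libraries of the same number, and 1 of 9 libraries correlated best with its own number. In simulations with 200 changed genes, changes of log2 0.5 were found in 9.52%, 9.23% and 5.97% of genes in the order of the contrasts. Changes of log2 2 were found in 95.3%, 93.2% and 93.9%, so it was mainly small changes that were missed there. The cause of each move was not tested, except where a stricter criterion made it.

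With pseudocount 0.1 the betaine against knockout comparison had 8 genes and knockout against wild type 5 lists; with pseudocount 1 betaine against knockout had 10 genes and the reversal 6. With no filter on low values, and 25420 genes tested, the gene counts were 1865 for knockout against wild type, 1 for betaine against knockout and 531 for betaine against wild type, and the reversal 1. Quantile normalization gave 3 lists for knockout against wild type and 5 for betaine against knockout. In TPM betaine against knockout had 1673 genes and the reversal 985. With eBayes without trend or robust, betaine against knockout had 0 genes (limma, 2670 at an unadjusted p under 0.05) and the reversal 0. Array weights, 0.284 for wild type replicate 3, 0.469 for betaine replicate 1 and 3.43 for wild type replicate 1, gave 5228, 2158 and 3208 genes in the order of the contrasts, a reversal of 1283 and 5 lists for knockout against wild type. With only the 2 groups compared, betaine against knockout had 35 genes and betaine against wild type 353. With the replicate block, knockout against wild type had 2210 genes, betaine against knockout 0 (limma, 2304 at an unadjusted p under 0.05), betaine against wild type 671 and the reversal 0. With the estimated inter-gene correlation 0, 0 and 0 lists were called by camera in limma. A log2 fold change of at least 1 left 702 genes for knockout against wild type and 329 for betaine against wild type. On own read totals betaine against knockout had 67 genes and the reversal 30. With wild type replicate 3 left out and the length trend removed, knockout against wild type had 1862 genes and 5 lists, betaine against knockout 205 genes and the reversal 63.

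As single libraries were left out, genes ranged from 897 to 3243 for knockout against wild type (lowest without knockout replicate 2), from 0 to 882 for betaine against knockout (0 without knockout replicates 2 or 3, limma, 1521 and 1993 at an unadjusted p under 0.05, and 882 without betaine replicate 1) and from 347 to 1439 for betaine against wild type (lowest without betaine replicate 3). The reversal ranged from 0 to 541, and the lists from 5 to 10, 7 to 10 and 8 to 12 in the order of the contrasts. The median of list female-biased liver genes, betaine-supplemented Cth knockout against wild type, ranged from -2.32 to 0.773 as single libraries were left out, and was 0.773 without wild type replicate 3 and 0.689 when the length trend was also removed. Those 2 values rest on the 4 of 16 genes that passed the filter without that library, so the change of sign comes with a change of members.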

Other observations

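The tests of sex-linked transcripts, of the length trend without wild type replicate 3, of RNA integrity, of feeding state and of time of day were chosen only after the result was seen, while the matched random lists and the other splits of the libraries were written before theirs.

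Libraries of one group also differed from each other in groups of genes. Among the betaine libraries, macrophage and Kupffer cell markers averaged -0.81 against the wild type mean in replicate 1, 0.38 in replicate 2 and 0.017 in replicate 3. Male-biased genes averaged 0.77 in betaine replicate 1 against 1.56 and 1.93 in replicates 2 and 3, and Cyp7b1, a male-biased bile acid enzyme, measured 53.2 FPKM there against 158 and 262 FPKM. Cyp2b9, which is female-biased, measured 37.3, 7.97 and 1.46 FPKM in the 3 betaine libraries and at most 1.05 FPKM in the knockout. Red blood cell markers averaged 1.63 in wild type replicate 2 and -1.48 in wild type replicate 3. The first principal component held 40.1% of the variance and the second 17.8%, and correlations between libraries ran from 0.893 to 0.981 across genes, which are not independent replicates.

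Wild type replicate 3 differed from the other wild type libraries in sex-linked transcripts. Its Cth, at 80.8% of the mean of the other wild type libraries, argues against a swap with a knockout library. Its 0 reads of 4 Y-linked genes allow at most 0.146% of the mean level of the other 8 libraries, with counting error only, which argues against male RNA mixed with female RNA. Xist at 26.6 FPKM, with the male-biased genes low and the female-biased ones high, is consistent with RNA of a female liver among 8 male ones. Whether the animal or only the label is out of place stays open, since the labels give no sex.

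Genes with long exons were lower, and oxidative phosphorylation and ribosomal protein genes higher, in the knockout than in wild type. Without wild type replicate 3 the correlation with exon length across genes was -0.436, so that library alone does not account for it. The median of 0.757 for oxidative phosphorylation genes lay above 99.9% of random lists matched on exon length and mean expression, and that of ribosomal proteins, 0.637, above 99.3%. The random medians were 0.417 and 0.349, so both lists rose more than most sets of genes of like length and expression. Random members were drawn independently, while members of the 2 lists vary together (estimated correlations of 0.645 and 0.668). These shares therefore do not decide whether the length trend is the whole cause. RNA integrity or library preparation may have differed between libraries: the length trend spanned 74.1% of the gap between the wild type and knockout means within the betaine libraries alone. It cannot be told apart from the knockout for the wild type and knockout libraries, whose trends, 0.223 to 0.369 and -0.382 to -0.290, did not overlap.

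Lipid synthesis genes were higher as lists (adjusted p = 0.945 with an estimated correlation), and Pck1, Angptl4 and Fgf21 had log2 fold changes of -1.78, -2.53 and -1.92 short of the threshold, with betaine than in the knockout. A candidate explanation is feeding state: the feeding-induced list had a median of 0.925 with 10 of 12 higher, while the fasting-induced list had a median of -0.35 with 10 of 16 lower. All 12 measured feeding genes and all 16 fasting genes also stand in the lists chosen beforehand, which makes this partly the same finding read another way. Among them 6 fasting genes went the other way. Feeding state is not labelled and would run with the group, so it and betaine cannot be told apart. Time of day could also differ, and the median of genes peaking with Dbp minus that of genes peaking with Arntl was -0.221. An SE of 0.178 was computed over genes for the difference of the list means, and it does not measure the spread between libraries. Time of day is left open. The labels give neither feeding nor time, and an effect of betaine on these genes stays untested beside them.

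Splits of 6 libraries into 3 against 3 number 10, too few for a share under 0.05. The real gene counts were 3029, 5 and 1381 in the order of the contrasts, and the highest other splits gave 1, 1 and 2, so that 1, 1 and 1 of 10 splits gave as many. The real list counts were 9, 8 and 9 against highest others of 15, 13 and 19, and 8, 6 and 9 of 10 splits gave as many lists. For the reversal, 3 of 100 drawn splits gave at least the real count of 3, the real one and 2 others, and each remaining split gave at most 1. When 2 groups were mixed between the sides of a single comparison, as counted above, fewer genes than 3 were called, so most splits could hardly match the real count and the share decides nothing about chance. The highest other, 899, and the next, 301, both had the 3 wild type libraries as the shared side, a structure of the samples in which the wild type stands apart from both knockout groups.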
